A study of Mus musculus with 16 samples.

How the data were processed

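Total RNA was extracted from adult mouse liver with guanidinium isothiocyanate, and pools of RNA from at least 5 mice per sex and genotype were labelled (5 ug) and hybridised to Affymetrix Mouse430_2 expression arrays at a university microarray core, per the labels. The mice ate standard chow. There were 8 groups, wild type, rsl null, Rsl1 transgene and Rsl2 transgene in males and females, with 2 arrays each. The values used were the authors' RMA log2 intensities, background corrected and quantile normalized by the authors, for 45100 probe sets. The version of their RMA software is not given in the sources used here. Whether pools share mice is unclear, so that p-values measure the spread between pools and not between mice. With 2 arrays per group, the number of arrays limits the precision.

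Probe sets were assigned to genes with the gene table supplied for the array. Of them 34958 had 1 symbol, 932 several and 9210 none there. Gene symbols were looked up in the RefSeq gene table of GRCm38.p6, which was used for names and for the order of neighbouring genes alone. In it 34754 probe set symbols and 18032 genes had a match. For each of 18193 genes the single-symbol probe set with the highest mean was taken (9012 genes had more than 1), and 13627 genes with a log2 intensity of at least 5 in at least 2 arrays were tested. The 4566 others were left out, and 64 control probe sets were used for RNA quality alone. Probe sets with several symbols, such as 1418021_at, were tested among all probe sets.

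Genes were tested with limma 3.58.1 in R 4.3.3 with the package data.table at version 1.17.8, with a mean for each of the 8 groups over the 16 arrays, 8 residual degrees of freedom, 5.225 prior degrees of freedom and Benjamini-Hochberg adjustment within each of 15 contrasts. Genes at adjusted p under 0.05 are called. Every test is two-sided, except the test of runs of genes and the counts over splits, which ask only for values at least as high. The contrasts were the sex difference in wild type; rsl null against wild type, Rsl1 transgene against rsl null and Rsl2 transgene against rsl null, each in males, in females and averaged over the sexes; the interaction of sex with each of these; and Rsl1 against Rsl2 transgene in each sex. Differences are female minus male, or the group named first minus the other, on the log2 scale. Each error of a log2 difference is limma's standard error.

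In all, 29 gene lists written from general knowledge were tested with camera at a preset correlation of 0.01 and adjusted within each contrast. Of 435 tests 120 passed. With a correlation estimated from the data 3 did: the male-biased, the female-biased and the sex chromosome list in the sex difference. A count adjusted over the list alone uses the members' p-values only. The lists covered sex-biased, sex chromosome, KRAB zinc finger, cholesterol, fatty acid, PPAR alpha, gluconeogenesis, bile acid, clock, acute-phase, interferon, MHC, xenobiotic, urea cycle, growth hormone, steroid, endoplasmic reticulum stress, heat shock and cell cycle genes, and markers of hepatocytes, Kupffer cells, lymphocytes, neutrophils and erythroid cells, stellate cells, endothelium, bile duct, pancreas and adipose tissue.

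Genes were named by a rule. In each main contrast these were the 10 largest positive and the 10 largest negative log2 differences among called genes, or, with none called, the 3 of smallest p. Rsl1, Rsl2 and their preset targets (Mup genes, C4a, C4b and Cyp2d9) were named in every comparison, and 2 to 4 members of smallest p in each list described. Groups, contrasts, lists, this rule and most of the alternatives below were fixed before the data were examined. C4a and C4b share their probe set here, and of the Mup genes Mup3, Mup5 and Mup10 had a probe set with 1 symbol. The other Mup genes were not tested by name.

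The steps were tested on 13627 simulated genes with 200 changed. For rsl null against wild type in males, 21 of 67 genes changed by a log2 of 0.5 were called. Of those changed by 1 and 2, 64 of 67 and 65 of 66 were, with 8 false calls. Averaged over the sexes these were 52 of 67, 66 of 67 and 65 of 66, with 10 false calls. No direction was wrong. Pools shifted in many genes were not simulated, and may add false calls.

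Alternatives were no filter, a filter at log2 of 7, a replicate block, the mean of all probe sets of a gene, probe sets ending in _x_at or _s_at left out, arrays quantile normalized again or centred on their medians, array weights, eBayes with trend and robust, arrays of the compared groups only, each array left out in turn, adjusted p under 0.01, a fold of at least 1.5 and an estimated correlation. For the overlaps they were males only, females only and the rsl null arrays split between both changes. Added after the data were seen were both doubted arrays left out, a clock index or the 3' to 5' actin difference as a covariate, and eBayes with trend only. Where leaving out 1 array left a group with 1, that array was assumed to vary like the other groups.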

Results

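Liver RNA of adult mice was measured on 16 expression arrays. The mice were of 4 genotypes in both sexes: wild type (B10.D2, Rsl/Rsl), the rsl null strain (B10.D2.PL, rsl/rsl), and rsl null mice that carried a liver transgene for Rsl1 or for Rsl2. Rsl1 and Rsl2 are KRAB zinc finger genes of the Regulator of sex-limitation locus, and the labels give sex-limited gene expression in the liver as the question. Each of the 8 groups of sex and genotype had 2 arrays, each of a pool of RNA. Median log2 intensity per array ran from 5.41 to 5.49, and 12627 to 13226 genes per array had a log2 intensity of at least 5. Pearson's r between the 2 arrays of a group ran from 0.989 to 0.997 across genes, which are not independent replicates. In a principal component analysis the first component (34.3% of the variance) separated females from males. Along the second component (15.5%) the 8 transgenic arrays lay between -17.6 and 0.603, and the 8 other arrays between 4.74 and 15.2.

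The sex of each array followed its label. Xist, which silences the X chromosome in females, had log2 intensities of 11.39 to 11.91 in the 8 female arrays and 4.81 to 5.68 in the 8 male arrays. Eif2s3y, carried by the Y chromosome, lay between 8.72 and 8.91 in males and between 3.0 and 3.45 in females. The Rsl1 probe set (1455292_x_at) read 4.55 to 5.29 in the 4 wild-type arrays and 3.58 to 3.93 in the 12 others. It was not raised in the 4 arrays labelled Rsl1 transgene. Whether it lies inside the transgene is not given in the sources used here, and if it lies outside, it checks nothing about that label. Zfp429, which the gene table lists as a synonym of Rsl2, read 6.66 and 9.18 in the males and 6.69 and 8.71 in the females with the Rsl2 transgene, and 3.81 to 5.01 in the 12 other arrays (1439475_at). The plot of Rsl1, Zfp429 and Zfp874a shows these values array by array.

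**Figure D1:**
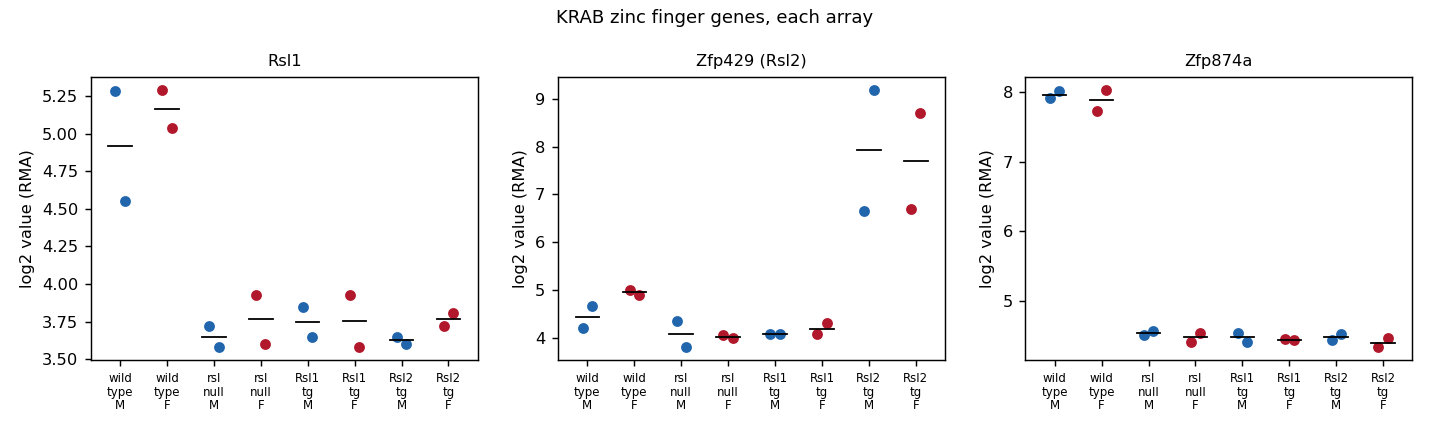
Log2 intensity of Rsl1, Zfp429 (Rsl2) and Zfp874a on the 16 arrays by group, with males in blue, females in red and a black line at the mean of the 2 pools. Zfp874a is high in the 4 wild-type arrays, Rsl1 is dim throughout and reads highest there, and Zfp429 is high in the 4 arrays of the Rsl2 transgene.

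Arrays of 2 female groups stood apart from the others of their genotype in genes outside the comparison. In rsl null female replicate 2 the mean of the pancreas markers, digestive enzymes of the exocrine pancreas for the most part, was 11.12, against 5.79 to 7.23 in the 15 other arrays. Prss2 reached 12.22 and Cpa1 11.13 there. In wild-type female replicate 1 the mean of the acute-phase genes, plasma proteins that the liver makes during inflammation, was 13.06 against 11.75 in replicate 2, and Lcn2 was 12.79 against 7.15. The difference between the 3' and 5' beta-actin control probe sets, a sign of RNA quality, averaged 1.75 ± 0.20 (SD, n = 2) in wild-type males and 1.77 ± 0.05 in wild-type females. It averaged 1.91 ± 0.10 in rsl null males and 2.18 ± 0.12 in rsl null females. With the Rsl1 transgene it was 1.95 ± 0.08 in males and 1.80 ± 0.06 in females, and with the Rsl2 transgene 1.85 ± 0.06 and 2.03 ± 0.15.

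Wild-type females and males were compared to measure the sex difference on which Rsl acts. Sulfotransferases and cytochrome P450 enzymes known from female liver were higher in females. Sult3a1 (1421669_at) was higher by a log2 difference of 7.13 ± 0.55 (SE, 2 arrays per group, adjusted p = 6.9e-06), Cyp2b9 (1419590_at) by 6.19 ± 0.39 (adjusted p = 9e-07) and Cyp2b13 by 6.09 ± 0.44. Enzymes known from male liver were lower in females: the fatty acid elongase Elovl3 at -5.07 ± 0.48 (adjusted p = 4.3e-05), the fatty acid hydroxylase Cyp4a12a at -4.51 ± 0.41, the steroid dehydrogenase Hsd3b5 at -3.37 ± 0.38, and Moxd1 at -5.72 ± 0.44. The metallothioneins Mt1 and Mt2, which bind zinc and copper, were higher in females by 4.12 ± 0.36 and 4.76 ± 0.56. Also among the 10 largest differences were Sult2a2 (7.97 ± 1.4), Xist (6.64), Acot3 (4.49), Cyp17a1 (3.56) and Slc22a26 (3.48) above, and Eif2s3y (-5.37), Ugt2b38 (-3.66), Kdm5d (-3.61), Snhg11 (-3.29), Nat8 (-3.22) and Asns (-3.06) below. Sult3a1, Sult2a2 and Xist in males and Moxd1, Eif2s3y and Kdm5d in females read near background, so these differences are lower bounds.

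Of 19 tested male-biased liver genes 17 fell and 0 rose in females (17 adjusted over the list alone, median -1.86, camera adjusted p = 4.2e-22, and adjusted p = 0.047 with an estimated correlation). Examples were C6 at -2.49 and Cyp7b1, an enzyme of the alternative bile acid pathway, at -1.86. Of 30 female-biased genes 21 rose and 0 fell (24 adjusted over the list alone, median 1.58, adjusted p = 1.1e-29, and adjusted p = 0.024 with an estimated correlation), Cyp2c38 at 1.65 ± 0.14 among them. Of 4 sex chromosome genes 1 rose and 3 fell (1 and 3 adjusted over the list alone, adjusted p = 0.00062, and adjusted p = 0.047 with an estimated correlation). Among known targets of Rsl, Cyp2d9, a steroid hydroxylase of male liver (1419349_a_at), was lower in females at -2.18 ± 0.43 (adjusted p = 0.012) and Mup10, a major urinary protein, at -1.01 ± 0.22 (adjusted p = 0.017). Mup3 (-0.21, adjusted p = 0.22), Mup5 (-0.08, adjusted p = 0.65) and the probe set 1418021_at, assigned to both C4a and C4b (-0.27, adjusted p = 0.24 over all probe sets), did not pass. Rsl1 (0.25, adjusted p = 0.48) and Zfp429 (0.51, adjusted p = 0.67) did not pass either.

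Macrophage genes were also higher in wild-type females. Of 15 Kupffer cell and macrophage markers 7 rose (9 adjusted over the list alone, median 0.43, camera adjusted p = 1.2e-07, and adjusted p = 0.31 with an estimated correlation), Vsig4 by 0.96 and Csf1r by 0.46. Of 24 acute-phase genes 4 rose (5 adjusted over the list alone, adjusted p = 2.4e-06, and adjusted p = 0.56 with an estimated correlation): Mt1, Mt2, Orm3 (2.05) and Orm2 (3.16). The acute-phase mean of wild-type female replicate 1, 13.06, stood beside both groups. In all, limma called 833 genes (6.11% of 13627 tested), 292 higher and 541 lower in females. Their balance turned with the scaling and with 1 array. With the arrays quantile normalized again the split was 387 and 343, and with each array centred on its median it was 213 and 712. Without wild-type male replicate 1, 245 genes passed, 136 higher and 109 lower, and without it Sult2a2 (adjusted p = 0.055) did not pass. Cyp2d9 lost its call without wild-type male replicate 1 (adjusted p = 0.082) or wild-type female replicate 1 (adjusted p = 0.067). Mup10 lost it without wild-type male replicate 1 (adjusted p = 0.10), wild-type male replicate 2 (adjusted p = 0.052) or wild-type female replicate 1 (adjusted p = 0.062), and the other 19 of the 22 genes named by the rule and called kept adjusted p under 0.05 with any 1 array left out.

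**Figure D2:**
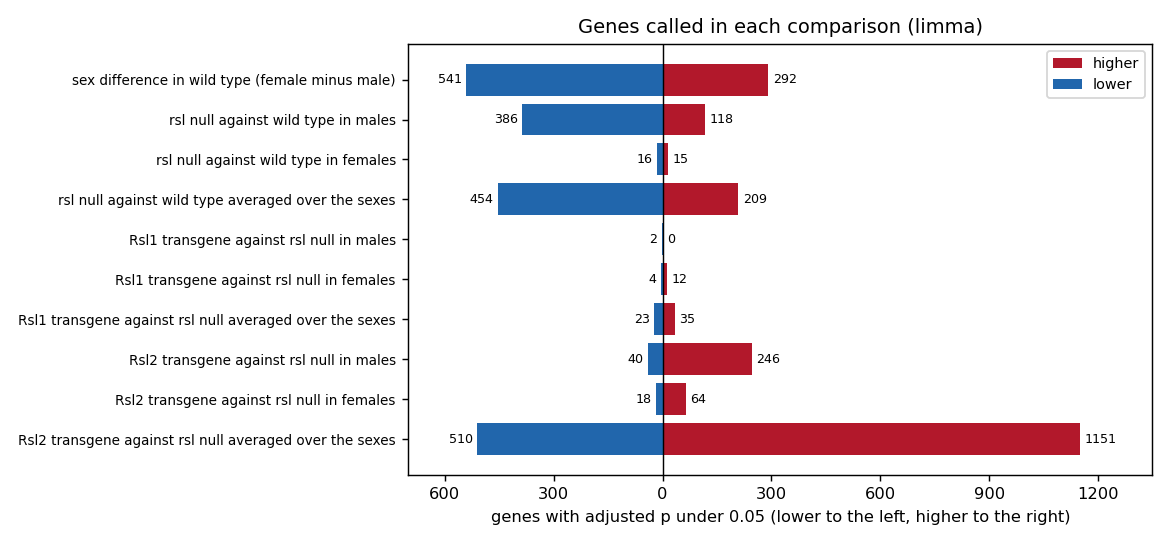
Number of genes called at adjusted p under 0.05 in 10 comparisons, as horizontal bars with genes higher in red and genes lower in blue. The averaged Rsl2 transgene comparison has the longest bar (1151 higher and 510 lower), and the Rsl1 transgene in males the shortest (0 and 2).

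The rsl null mice were compared with wild type to find genes whose level differs in liver of the rsl strain. Averaged over the sexes, the zinc finger gene Zfp874a, a neighbour of Rsl1, fell by 3.41 ± 0.077 (log2, SE, 4 arrays against 4, adjusted p = 1.2e-11, 1434171_at). It read 7.73 to 8.03 in wild type and 4.34 to 4.57 in the 12 other arrays. Rsl1 itself, dim in wild type as well (4.55 to 5.29), fell by 1.33 ± 0.14 (adjusted p = 0.00018), and Zfp429 was at -0.65 (adjusted p = 0.46). Hddc3, a hydrolase (1428692_at), rose by 2.81 ± 0.12 (adjusted p = 1.4e-08), the peptide transporter Slc15a2 by 2.39 ± 0.12, Crym, which binds thyroid hormone, by 2.38 ± 0.16, and the thiopurine methyltransferase Tpmt by 1.89 ± 0.095 (adjusted p = 1e-07). The predicted gene Gm7969 fell by 5.05 ± 0.20, and the tripartite motif genes Trim30d, Trim34a and Trim12a fell, at -3.25 ± 0.30, -2.45 ± 0.25 and -1.92 ± 0.15. Zfp874a, Rsl1, Gm7969, Trim30d and Trim12a in rsl null liver and Hddc3 (5.17 to 5.80), Crym and Cap2 in wild type read near background. These differences are therefore lower bounds, here and within each sex, if the probes match the RNA of both strains alike, which was not tested.

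Genes of the circadian clock differed between these genotypes. Of 17 tested, 8 rose and 3 fell (9 and 4 adjusted over the list alone, median 0.44, camera adjusted p = 0.0058, and adjusted p = 0.45 with an estimated correlation). Per3, a repressor of the clock (1421087_at), rose by 1.75 ± 0.27 (adjusted p = 0.004), and Dbp, a transcription factor under clock control, by 1.29 ± 0.24. Arntl, an activator of the clock that peaks opposite to them, fell by 1.88 ± 0.32 (adjusted p = 0.0067). In the same average Usp2, a deubiquitinase with a daily rhythm, rose by 1.87 ± 0.34, and Per2 by 1.55 ± 0.36, and neither was called in females (0.97 ± 0.49 and 1.16 ± 0.51). On a clock index, the mean of Per2, Per3 and Dbp minus the mean of Arntl and Clock, the wild-type males read -0.04 and -0.72 and the wild-type females -0.06 and 2.93. The 4 rsl null arrays read 3.03 to 3.83, those labelled Rsl1 transgene 2.58 to 3.01, and those of the Rsl2 transgene 1.38 and 2.34 in males and 3.34 and 3.05 in females (index chosen after the values were seen). In females alone 0 of the 17 clock genes were called (3 higher and 1 lower adjusted over the list alone, median 0.46, adjusted p = 0.028, and adjusted p = 0.58 with an estimated correlation).

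Averaged over the sexes, genes of cholesterol synthesis were lower in rsl null liver. Of 20 tested 8 fell and 0 rose (15 adjusted over the list alone, median -0.29, camera adjusted p = 2.1e-08, and adjusted p = 0.45 with an estimated correlation). Phosphomevalonate kinase, Pmvk, fell by 0.69 ± 0.076 (adjusted p = 0.00029), Hmgcs1, which makes the precursor of mevalonate, fell by 0.66, and Dhcr7, which catalyses the last step, fell by 0.54. In females alone 0 of the 20 were called (1 higher adjusted over the list alone, median 0.00, adjusted p = 0.39), with Hmgcs1 at -0.01 ± 0.15 and Pmvk at -0.16 ± 0.11, and 6 of the 20 passed the test of the interaction with sex. Of 15 Kupffer cell markers 1 rose and 3 fell (1 and 5 adjusted over the list alone, median -0.25, adjusted p = 0.0058, and adjusted p = 0.70 with an estimated correlation): Cd163 rose by 0.62 and C1qa, C1qb and C1qc fell, at -0.36, -0.42 and -0.32. Of 10 MHC genes 1 fell (3 adjusted over the list alone, adjusted p = 0.0081, and adjusted p = 0.70 with an estimated correlation), H2-Q10 at -0.22. The pancreas markers had a median of 0.90 with 0 of 11 called (0 adjusted over the list alone, adjusted p = 0.035, and adjusted p = 0.72 with an estimated correlation), beside the mean of 11.12 in rsl null female replicate 2.

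Of 19 male-biased genes 1 rose, the bile acid and steroid transporter Slco1a1 by 0.83 ± 0.15 (adjusted p = 0.01). Adjusted over the list alone 5 rose and 1 fell (median 0.18, camera adjusted p = 0.011, and adjusted p = 0.70 with an estimated correlation). Of 30 female-biased genes 1 rose and 4 fell (2 and 6 adjusted over the list alone, adjusted p = 0.85), among them Cyp2b10, an enzyme of drug metabolism, which fell by 1.55 ± 0.25 (adjusted p = 0.0055). The preset targets tested here did not pass limma's test: Cyp2d9 was at 0.27 (adjusted p = 0.68), Mup10 at 0.01 (adjusted p = 0.98), Mup3 at -0.08 (adjusted p = 0.55), Mup5 at -0.13 (adjusted p = 0.29) and 1418021_at at 0.06 (adjusted p = 0.78). Of 13 KRAB zinc finger genes of the Rsl cluster 2 rose and 2 fell (4 and 2 adjusted over the list alone, adjusted p = 0.80), with Zfp729a up by 0.96 ± 0.074 and Zfp759 up by 0.45.

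In all, 663 genes were called (4.87%), 209 higher and 454 lower in rsl null liver, and 321 and 448 with the arrays quantile normalized again. The other genes of the 10 largest rises were Erdr1 (2.07 ± 0.24), Cap2 (1.92 ± 0.16) and Coq10b (1.48 ± 0.30), and of the 10 largest falls Tubb2a (-2.02), Chka (-1.75) and Denn2b (-1.62). Erdr1 was at -0.04 with probe sets ending in _x_at or _s_at left out. Of 21 named and called genes 19 kept adjusted p under 0.05 with any 1 array left out. Coq10b lost its call without rsl null male replicate 1 or 2 (adjusted p = 0.058 and 0.065). Per2 lost it without wild-type male replicate 1 or 2 (adjusted p = 0.053 and 0.074), rsl null male replicate 1 or 2 (0.095 and 0.082) or rsl null female replicate 1 or 2 (0.071 and 0.058). The count was 291 without wild-type male replicate 1, 387 without wild-type female replicate 1, 1072 without wild-type female replicate 2, 203 and 215 without rsl null male replicate 1 or 2, and 374 without rsl null female replicate 2. With both wild-type female replicate 1 and rsl null female replicate 2 left out, chosen after seeing the data, 314 genes passed.

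**Figure D3:**
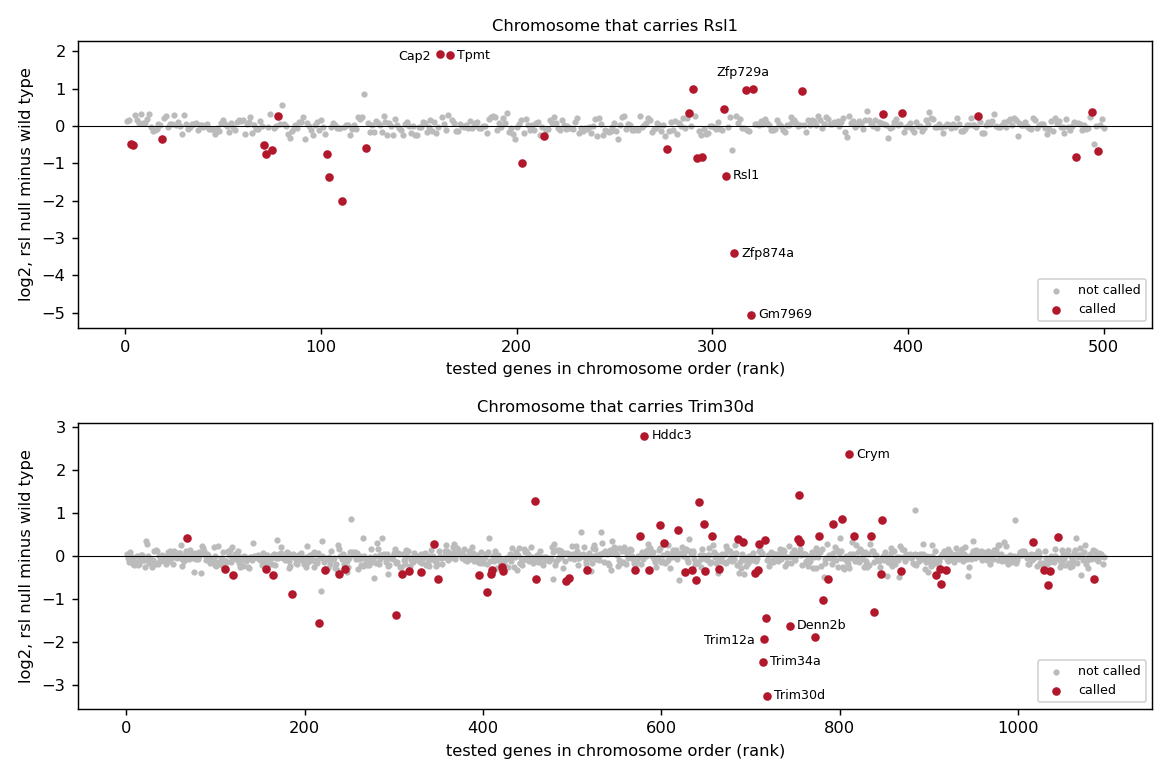
Log2 difference of rsl null from wild type, averaged over the sexes, for each tested gene in the order of the genes along the chromosome that carries Rsl1 and along the chromosome that carries Trim30d. Called genes are marked, and those with the largest differences, such as Zfp874a (-3.41) and Trim30d (-3.25), are named.

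In males alone, rsl null liver differed from wild type in 504 genes, 118 higher and 386 lower. Hddc3 rose by 2.70 ± 0.17 (adjusted p = 1.9e-06), Slc15a2 by 2.68 ± 0.17 and the pseudoautosomal gene Erdr1 by 2.50 ± 0.33, and Zfp874a fell by 3.43 ± 0.11 (adjusted p = 1.1e-09). Pdk4, a kinase that restrains glucose oxidation, fell by 2.39 ± 0.33, and Cyp4a14, a fatty acid hydroxylase under PPAR alpha, fell by 2.19 ± 0.36. Of the 20 genes of cholesterol synthesis 11 fell (17 adjusted over the list alone, median -0.62, camera adjusted p = 5.5e-17, and adjusted p = 0.11 with an estimated correlation), Hmgcs1 at -1.32 ± 0.15 (adjusted p = 0.00054), Pmvk at -1.21 ± 0.11 and Sqle, squalene epoxidase, at -1.06. Of 20 genes of fatty acid synthesis 2 rose and 5 fell (3 and 10 adjusted over the list alone, adjusted p = 0.016, and adjusted p = 0.84 with an estimated correlation): the malic enzyme Me1 fell by 1.15 ± 0.16, and Lpin1, which makes diacylglycerol, rose by 1.83. Of 17 clock genes 5 rose and 2 fell (8 and 3 adjusted over the list alone, adjusted p = 0.0094, and adjusted p = 0.54 with an estimated correlation), with Per3 up by 2.21 ± 0.38 and Arntl down at -2.11 ± 0.46 (adjusted p = 0.024).

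Others of the largest differences in males were Usp2 (2.78 ± 0.49), Coq10b (2.21), Crym (2.16), Ces2b (2.13), Rgs16 (2.11) and Wee1 (1.97) above, and Gm7969 (-5.58), Trim30d (-3.25), Serpinb1a (-2.59), Tubb2a (-2.58), Trim34a (-2.43) and Ighm (-2.09) below. Rsl1 fell by 1.27 ± 0.20 (adjusted p = 0.004), a call lost without rsl null male replicate 2 (adjusted p = 0.058). Zfp429 was at -0.37 (adjusted p = 0.81). Of 21 named and called genes 11 kept adjusted p under 0.05 with any 1 array left out: Hddc3, Slc15a2, Erdr1, Crym, Rgs16, Gm7969, Zfp874a, Trim30d, Trim34a, Pdk4 and Cyp4a14. The count of 504 became 123 without wild-type male replicate 1, 81 without rsl null male replicate 1 and 93 without rsl null male replicate 2. With the arrays quantile normalized again the split was 176 higher and 266 lower. With the clock index as a covariate, chosen after seeing the data, 28 genes passed, 6 higher and 22 lower. The differences were then 0.8 of their size at the median (quartiles 0.44 to 1.13).

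In females 31 genes were called, 15 higher and 16 lower in rsl null liver. Hddc3 rose by 2.91 ± 0.17 (adjusted p = 1.1e-06), Crym by 2.59 ± 0.22, Cap2, which binds actin, by 2.21 ± 0.23 and Tpmt by 2.19 ± 0.13 (adjusted p = 1.5e-06). Slc15a2 rose by 2.11 ± 0.17 and Zfp729a by 1.06 ± 0.10. Zfp874a fell by 3.40 ± 0.11 (adjusted p = 1.2e-09), Gm7969 fell by 4.52 ± 0.28, Trim30d fell by 3.24 ± 0.43, Trim34a fell by 2.47, Trim12a fell by 2.04 ± 0.21 and Trim30a fell by 1.37. Cdk5rap1 (1.08), Thumpd1 (0.98), Slc35d2 (0.89), Fabp2 (0.82), Loxl4 (-1.17), Ethe1 (-0.91) and Prxl2c (-0.88) completed the largest differences. Rsl1 fell by 1.40 ± 0.20 (adjusted p = 0.0059), a call lost without wild-type female replicate 1 (adjusted p = 0.095) or rsl null female replicate 2 (adjusted p = 0.064). The histidine lyase Hal fell by 0.76 (adjusted p = 0.017), the only gene called among 20 of the urea cycle and amino acid breakdown (4 adjusted over the list alone, camera adjusted p = 0.0066, and adjusted p = 0.58 with an estimated correlation).

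These lists passed camera in females at the preset correlation and not with an estimated one, with 0 members called. The male-biased genes had a median of 0.30 with 0 of 19 called (5 adjusted over the list alone, camera adjusted p = 0.0011, and adjusted p = 0.58 with an estimated correlation). The Kupffer cell markers had a median of -0.34 with 0 of 15 called (1 higher and 5 lower adjusted over the list alone, adjusted p = 0.00014, and adjusted p = 0.58 with an estimated correlation). The pancreas markers had a median of 1.99 with 0 of 11 called (adjusted p = 0.00014, and adjusted p = 0.58 with an estimated correlation), and the acute-phase genes -0.19 with 0 of 24 called (adjusted p = 0.002, and adjusted p = 0.80 with an estimated correlation). Pancreas mean 11.12 in rsl null female replicate 2 and acute-phase mean 13.06 in wild-type female replicate 1 belong to these groups. Of 20 named and called genes 11 kept adjusted p under 0.05 with any 1 array left out: Hddc3, Crym, Cap2, Tpmt, Slc15a2, Zfp729a, Slc35d2, Gm7969, Zfp874a, Trim12a and Prxl2c. Prxl2c was at 0.08 with the mean of its probe sets. The count was 11 without wild-type female replicate 1, 438 without wild-type female replicate 2 (256 higher and 182 lower), 70 without rsl null female replicate 1 (57 and 13), and 18 with both doubted arrays left out (chosen after seeing the data).

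The difference between the sexes in this effect was tested as an interaction. Limma called 12 genes, and in each the female effect minus the male effect was positive. Of them 6 belong to cholesterol synthesis: Hmgcs1 at 1.32 ± 0.21 (adjusted p = 0.043), Sqle at 1.21 ± 0.20, Cyp51 at 1.07 ± 0.15, Pmvk at 1.05 ± 0.15, Idi1 at 1.04 ± 0.15 and Fdft1 at 1.01. Of the 20 genes of that list 13 passed adjusted over the list alone (median 0.77, camera adjusted p = 1.1e-18, and adjusted p = 0.087 with an estimated correlation). The others were Ccdc25 (2.17 ± 0.26), Rdh11 (1.78), Lgals1 (1.73), Fmn1 (1.5), Pltp (1.31), which moves phospholipids between lipoproteins, and Mmab (0.96). The count was 4 without wild-type male replicate 1, 0 without wild-type male replicate 2, 58 and 36 without wild-type female replicate 1 or 2, 0 and 5 without rsl null male replicate 1 or 2, and 57 and 29 without rsl null female replicate 1 or 2. At an unadjusted p under 0.05 it was 1384, and 0 of the 10 named genes kept their call with any 1 array left out.

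**Figure D4:**
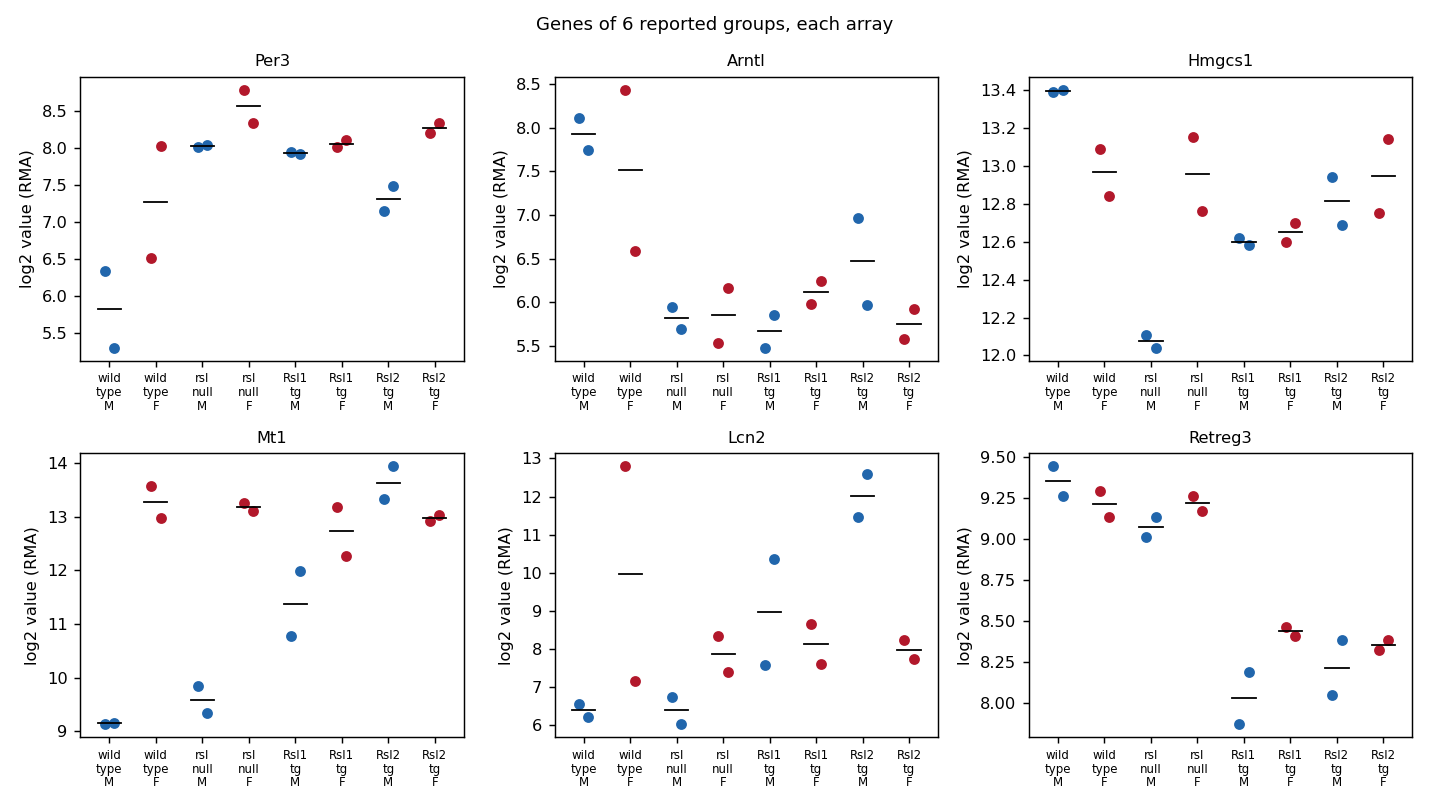
Log2 intensity of Per3, Arntl, Hmgcs1, Mt1, Lcn2 and Retreg3 on the 16 arrays by group, with males in blue, females in red and a black line at the mean of the 2 pools. Retreg3 lies between 7.87 and 8.46 in the 8 transgenic arrays and between 9.01 and 9.44 in the 8 others.

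Mice labelled Rsl1 transgene were compared with rsl null mice to find genes that change when Rsl1 is put back. Averaged over the sexes, limma called 58 genes, 35 higher and 23 lower. Ppp1r3b, which targets a phosphatase to glycogen, fell by 1.21 ± 0.14 (4 arrays against 4, adjusted p = 0.0026), the RING finger gene Lonrf3 fell by 1.37 ± 0.17, Retreg3, a receptor for turnover of the endoplasmic reticulum (1424159_at), fell by 0.91 ± 0.093 (adjusted p = 0.0019), Setd5 fell by 0.81 ± 0.085 and the exoribonuclease Xrn1 fell by 0.78 ± 0.094. Clec2d fell by 1.00 ± 0.14 and Apob, the core protein of secreted lipoproteins, fell by 0.68 ± 0.10. Agfg2 rose by 0.89 ± 0.12, the gasdermin Gsdme by 0.69 ± 0.088 and the RNA-binding gene Raly by 0.68 ± 0.091. Trim30d rose by 1.81 ± 0.30 (adjusted p = 0.021), a lower bound. It read 6.37 to 7.63 in the 4 arrays labelled Rsl1 transgene, between the rsl null arrays (4.73 to 5.05, near background) and the wild-type arrays (7.81 to 8.51). With the Rsl2 transgene it read 5.99 and 6.53 in males and 5.06 and 6.51 in females. Trim30d lies in the run of genes between Rhog and Adm, described below as a possible donor block. Arhgap26 (0.90), Neat1 (0.85), Trib3 (0.76), Mpst (0.75), Dnase2a (0.74) and Malt1 (0.66) were the other large rises, and Fnip2 (-0.69), Ap2b1 (-0.62) and Nufip2 (-0.60) the other large falls.

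Neither Rsl1 nor the preset targets tested here passed: Rsl1 was at 0.04 (adjusted p = 0.90), Cyp2d9 at 0.44 (adjusted p = 0.49), Mup3 at 0.19 (adjusted p = 0.20), Mup5 at -0.03 (adjusted p = 0.88), Mup10 at 0.08 (adjusted p = 0.84), Zfp429 at 0.09 (adjusted p = 0.95) and 1418021_at at -0.24 (adjusted p = 0.21). Of 30 female-biased genes 1 fell, the monooxygenase Fmo1 at -0.32 (3 adjusted over the list alone, median -0.32, camera adjusted p = 2.7e-06, and adjusted p = 0.62 with an estimated correlation). The male-biased genes had a median of 0.23 with 0 of 19 called (0 adjusted over the list alone, adjusted p = 0.00046, and adjusted p = 0.62 with an estimated correlation). The Kupffer cell markers had a median of 0.17 with 0 of 15 called (4 adjusted over the list alone, adjusted p = 0.00046, and adjusted p = 0.62 with an estimated correlation). The pancreas markers had a median of -1.44 (adjusted p = 0.0013, and adjusted p = 0.62 with an estimated correlation), beside the 11.12 of rsl null female replicate 2. Of 20 named and called genes 9 kept adjusted p under 0.05 with any 1 array left out: Agfg2, Gsdme, Raly, Lonrf3, Ppp1r3b, Clec2d, Retreg3, Setd5 and Xrn1. The count was 14 and 26 without rsl null male replicate 1 or 2, 30 and 20 without Rsl1 transgene male replicate 1 or 2, 21 and 31 without Rsl1 transgene female replicate 1 or 2, 0 with the actin difference as a covariate (the differences kept 0.924 of their size at the median), and 217 with both doubted arrays left out (both chosen after seeing the data). With each array centred on its median, 73 genes were higher and 18 lower. Without rsl null female replicate 1 the balance turned, with 25 higher and 53 lower. It also turned without rsl null male replicate 1 (6 and 8), Rsl1 transgene male replicate 1 or 2 (14 and 16, 9 and 11) and Rsl1 transgene female replicate 1 (10 and 11).

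By sex, 2 genes were called in males labelled Rsl1 transgene, Retreg3 at -1.04 ± 0.13 (adjusted p = 0.031) and Xrn1 at -0.95 ± 0.13 (adjusted p = 0.047), and 1036 genes had an unadjusted p under 0.05. The acute-phase genes had a median of 0.21 in males with 0 of 24 called (2 adjusted over the list alone, camera adjusted p = 1.1e-07, and adjusted p = 0.62 with an estimated correlation). The genes of cholesterol synthesis had a median of 0.15 with 0 of 20 called (6 adjusted over the list alone, adjusted p = 7.1e-07, and adjusted p = 0.55 with an estimated correlation). In females 16 genes were called, 12 higher and 4 lower, against 7 higher and 43 lower without rsl null female replicate 1. Trib3, a pseudokinase induced by amino acid and endoplasmic reticulum stress, rose by 1.43 ± 0.18 (adjusted p = 0.02), and Syvn1, a ubiquitin ligase of the endoplasmic reticulum, by 0.86. Lonrf3 fell by 1.79 ± 0.24, Ppp1r3b fell by 1.29 ± 0.19, Setd5 fell by 0.83 and Retreg3 fell by 0.78. Raly (0.84), Rbpms (0.79), Krt10 (0.76), Glt28d2 (0.74), Gsdme (0.73), Ctse (0.69), C1qb (0.69, adjusted p = 0.046) and Lsm2 (0.67) also rose, and Ctse was at -0.40 with probe sets ending in _x_at or _s_at left out. With arrays of the compared groups only, 0 genes were called in these females. Cyp2d9 in females was at 1.00 (adjusted p = 0.30).

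Both lists of sex-biased genes passed camera in these females at the preset correlation and not with an estimated one, with 0 genes called. Of 19 male-biased genes 0 were called (10 higher adjusted over the list alone, median 0.53, camera adjusted p = 1.1e-06, and adjusted p = 0.39 with an estimated correlation). Of 30 female-biased genes 0 were called (1 higher and 10 lower adjusted over the list alone, median -0.47, adjusted p = 2.3e-10, and adjusted p = 0.39 with an estimated correlation). Kupffer cell markers had a median of 0.34 with 1 of 15 called (8 adjusted over the list alone, adjusted p = 8.6e-07, and adjusted p = 0.39 with an estimated correlation). In the same comparison the pancreas markers had a median of -2.78 with 0 of 11 called (10 lower adjusted over the list alone, adjusted p = 5.7e-07, and adjusted p = 0.47 with an estimated correlation). None of the 2 genes in males or the 14 named genes in females kept its call with any 1 array left out. In males the count was 0 without rsl null male replicate 1, rsl null male replicate 2 or Rsl1 transgene male replicate 1. In females it was 50 and 45 without rsl null female replicate 1 or 2, 0 without Rsl1 transgene female replicate 1 or 2, and 132 with both doubted arrays left out (chosen after seeing the data). The interaction of sex with this effect called 0 genes in limma, and 725 had an unadjusted p under 0.05. Those of smallest p, which did not pass, were Ctse (1.00, adjusted p = 0.14), Sqle (-1.24, adjusted p = 0.19) and Cyp51 (-0.85, adjusted p = 0.25). Without rsl null female replicate 1 that count was 38, without rsl null female replicate 2 it was 17, and without Rsl1 transgene male replicate 1 it was 2.

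Rsl2 transgenic mice were compared with rsl null mice to find genes that change when Rsl2 is put back. Averaged over the sexes, the transgene's own gene Zfp429 rose by 3.76 ± 0.46 (4 arrays against 4, adjusted p = 0.0014), a lower bound here and within each sex, as the rsl null arrays read near background at 3.81 to 4.35. Acute-phase and metal-binding genes rose: Orm2 by 2.42 ± 0.57, Mt2 by 2.26 ± 0.39, Mt1 by 1.92 ± 0.26 (adjusted p = 0.0022) and Saa3, an acute-phase amyloid protein, by 1.86 ± 0.34. Of these 4 genes none was called in females, where Mt1 was at -0.20 ± 0.36, Mt2 at 0.09 ± 0.56, Saa3 at 0.11 ± 0.49 and Orm2 at 0.78 ± 0.80 (adjusted p = 0.79, 0.95, 0.92 and 0.62). Mt1 passed the test of the interaction with sex, and the other 3 did not. Lonrf3 fell by 1.56 ± 0.17 (adjusted p = 0.00077), Ppp1r3b fell by 1.14 ± 0.14, Clec2d fell by 1.08, Xrn1 fell by 1.03 ± 0.094 (adjusted p = 0.00041) and Acot3, a thioesterase of fatty acid metabolism, fell by 1.07 ± 0.27. Mmd2 (1.58), Atp11a (1.55), the immediate early gene Egr1 (1.42), Slc41a2 (1.32) and Tubb2a (1.26) were the other large rises, and Wee1 (-0.97), Col27a1 (-0.96), Noct (-0.92), Nrep (-0.91) and G0s2 (-0.91) the other large falls.

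Macrophage genes rose with the Rsl2 transgene. Of 15 Kupffer cell markers 8 rose (13 adjusted over the list alone, median 0.38, camera adjusted p = 3.5e-06, and adjusted p = 0.65 with an estimated correlation): C1qb by 0.47 (adjusted p = 0.007), C1qa by 0.38, C1qc by 0.40 and Cd68 by 0.54. In females alone 0 were called (4 higher adjusted over the list alone, median 0.24, adjusted p = 0.0046, and adjusted p = 0.69 with an estimated correlation). Of 24 acute-phase genes 7 rose (10 adjusted over the list alone, median 0.36, adjusted p = 1.9e-05, and adjusted p = 0.65 with an estimated correlation), and in females alone 0 were called (0 adjusted over the list alone, median 0.02, adjusted p = 0.86). Of 20 genes of fatty acid synthesis 4 fell (4 adjusted over the list alone, median -0.14, adjusted p = 0.012, and adjusted p = 0.65 with an estimated correlation): fatty acid synthase, Fasn, fell by 0.47, its regulator Srebf1 fell by 0.40, Pklr fell by 0.32 and Gpam fell by 0.28. Of 25 genes of PPAR alpha and fatty acid oxidation 3 fell (4 adjusted over the list alone, adjusted p = 0.019, and adjusted p = 0.65 with an estimated correlation), Acot3, Acadm (-0.28) and Hadhb (-0.21), and Hadhb was at 0.21 with the mean of its probe sets. Of 30 female-biased genes 3 fell (8 adjusted over the list alone, median -0.23, adjusted p = 0.008, and adjusted p = 0.65 with an estimated correlation), Fmo1 at -0.35 and Cyp2c39 at -0.31 among them. The pancreas markers had a median of -1.46 with 0 of 11 called (adjusted p = 0.008, and adjusted p = 0.65 with an estimated correlation), beside the 11.12 of rsl null female replicate 2.

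The preset targets tested here did not pass: Cyp2d9 was at 0.23 (adjusted p = 0.64), Mup3 at 0.13 (adjusted p = 0.20), Mup5 at 0.00 (adjusted p = 0.98), Mup10 at 0.07 (adjusted p = 0.78) and 1418021_at at -0.27 (adjusted p = 0.056), and neither did Rsl1 at -0.01 (adjusted p = 0.96). In all, 1661 genes were called (12.2%), 1151 higher and 510 lower. The split was 693 and 648 with the arrays quantile normalized again and 1800 and 296 with each array centred on its median. Of 20 named and called genes 11 kept adjusted p under 0.05 with any 1 array left out: Zfp429, Mt2, Mt1, Saa3, Mmd2, Atp11a, Lonrf3, Ppp1r3b, Clec2d, Xrn1 and Col27a1. The count was 277 and 945 without rsl null male replicate 1 or 2, 696 without rsl null female replicate 1, 443 without Rsl2 transgene male replicate 2 and 419 without Rsl2 transgene female replicate 2. With both doubted arrays left out, chosen after seeing the data, it was 1700.

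In males 286 genes were called, 246 higher and 40 lower. Lcn2, an iron-chelating acute-phase protein, rose by 5.63 ± 1.3 (adjusted p = 0.044), Mt1 by 4.04 ± 0.36 (adjusted p = 6e-04), Mt2 by 4.43 ± 0.56, Orm2 by 4.06 ± 0.80, Saa3 by 3.62 ± 0.49 and Zfp429 by 3.84 ± 0.65 (adjusted p = 0.016). Xrn1 fell by 1.19 ± 0.13 (adjusted p = 0.0027). Of 24 acute-phase genes 7 rose (16 adjusted over the list alone, median 0.68, camera adjusted p = 9e-12, and adjusted p = 0.47 with an estimated correlation). Their mean per array was 12.74 and 13.20, against 11.57 and 11.37 in rsl null males and 11.74 and 12.44 in males labelled Rsl1 transgene. Of 15 Kupffer cell markers 4 rose (11 adjusted over the list alone, median 0.52, adjusted p = 2.2e-08, and adjusted p = 0.47 with an estimated correlation), C1qa, C1qb and C1qc by 0.52, 0.54 and 0.55 and Mpeg1 by 0.72. Of 20 genes of cholesterol synthesis 5 rose (8 adjusted over the list alone, median 0.19, adjusted p = 0.00079, and adjusted p = 0.47 with an estimated correlation), Sqle by 0.95 ± 0.14 and Hmgcs1 by 0.74.

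The other large rises in Rsl2 transgenic males were Atp11a (2.38), Mmd2 (2.09), Tubb2a (1.74) and Cpne8 (1.70). The other large falls were Rgs16 (-1.41), Lonrf3 (-1.41), Clec2d (-1.02), Col27a1 (-1.01), Map2k6 (-0.98), Osbpl3 (-0.96), Fnip2 (-0.96), Cnmd (-0.88) and Setd5 (-0.88). Of 20 named and called genes, Mt1 alone kept adjusted p under 0.05 with any 1 array left out. The count was 1 without rsl null male replicate 1, 32 without rsl null male replicate 2, 97 and 4 without Rsl2 transgene male replicate 1 or 2, 45 with the clock index as a covariate (the differences kept 0.95 of their size at the median), and 588 with both doubted arrays left out (both chosen after seeing the data). With the arrays quantile normalized again 104 genes were higher and 43 lower.

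In females 82 genes were called with the Rsl2 transgene, 64 higher and 18 lower, against 9 higher and 48 lower without rsl null female replicate 1. Zfp429 rose by 3.67 ± 0.65 (adjusted p = 0.029), Trib3 by 1.77 ± 0.18 (adjusted p = 0.0032), Dpy19l3 by 1.74, Agfg2 by 1.35, the transcription factor Foxp1 by 1.06 and Gsdme by 1.04. Lonrf3 fell by 1.71 ± 0.24 (adjusted p = 0.011), Ppp1r3b fell by 1.45, Clec2d fell by 1.15, Retreg3 fell by 0.86 and Esr1, the estrogen receptor alpha, fell by 0.74 (adjusted p = 0.05). Dnase2a (1.03), Mpst (1.00), Bach2 (1.00) and Nlrp12 (0.98) were the other large rises, and Col27a1 (-0.91), Setd5 (-0.88), Xrn1 (-0.88), Olfr157 (-0.74) and Tsks (-0.61) the other large falls. Of 30 female-biased genes 1 fell, Fmo1 at -0.51 (7 adjusted over the list alone, median -0.37, camera adjusted p = 1.6e-05, and adjusted p = 0.69 with an estimated correlation). The male-biased genes had a median of 0.38 with 0 of 19 called (3 adjusted over the list alone, adjusted p = 0.013, and adjusted p = 0.69 with an estimated correlation). The pancreas markers had a median of -2.80 (10 of 11 lower adjusted over the list alone, adjusted p = 1.6e-05, and adjusted p = 0.69 with an estimated correlation).

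Of 20 named and called genes in these females, Trib3 alone kept adjusted p under 0.05 with any 1 array left out. The count was 35 without Rsl2 transgene female replicate 1, 2 without Rsl2 transgene female replicate 2, 5 with the actin difference as a covariate (the differences kept 0.978 of their size at the median), and 255 with both doubted arrays left out (both chosen after seeing the data). With the arrays quantile normalized again the split was 39 and 25, and with each array centred on its median 149 and 16. With arrays of the compared groups only, 0 genes were called. The interaction of sex with the Rsl2 effect called 1 gene in limma, Mt1 at -4.25 ± 0.51 (adjusted p = 0.019), and 753 had an unadjusted p under 0.05. The count was 0 with the mean of all probe sets of a gene and 0 with probe sets ending in _x_at or _s_at left out. With no filter it was 5. Mt1 read 13.33 and 13.94 in Rsl2 transgenic males, 9.84 and 9.34 in rsl null males, and 12.27 to 13.57 in the 8 female arrays. Of 24 acute-phase genes 7 were lower in this interaction adjusted over the list alone (median -0.65, camera adjusted p = 1.9e-14, and adjusted p = 0.30 with an estimated correlation). The count of 1 became 0 without rsl null male replicate 1, rsl null male replicate 2 or Rsl2 transgene male replicate 2, 41 and 16 without rsl null female replicate 1 or 2, and 4 without Rsl2 transgene male replicate 1.

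The transgenes were compared with each other and with the rsl null change. Of the 58 genes called with the Rsl1 transgene, 57 were called in the same direction with the Rsl2 transgene and 0 in the opposite one, Lonrf3, Ppp1r3b, Retreg3 and Xrn1 among the shared falls (3.82 and 3.25 expected by chance). The 2 changes share the rsl null arrays. With all arrays r across genes was 0.856, against 0.503 in simulated unchanged groups that share these arrays in the same way. With the rsl null arrays split between the changes, which then share no array, r was 0.594 and 0.537. In these splits 9 and 12 genes were shared in the same direction (0.0471 and 0.555 expected by chance). Direct comparison of the transgenes by limma called 0 genes in males (1251 with unadjusted p under 0.05) and 0 in females (478). The genes of smallest p in males, which did not pass, were Cpne8 (-1.20), Mt1 (-2.25) and Zfp429 (-3.84), each with adjusted p = 0.19. In females they were Ctse (0.58), Zfp429 (-3.50) and 4930456A14Rik (-0.47), with adjusted p = 0.80, 0.80 and 1. In males 2 genes were called without Rsl1 transgene male replicate 2, and 4 and 1 without Rsl2 transgene male replicate 1 or 2.

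Between the transgenes the Kupffer cell markers had a median of -0.51 in males for Rsl1 minus Rsl2, with 0 of 15 called (13 lower adjusted over the list alone, camera adjusted p = 1e-12, and adjusted p = 0.49 with an estimated correlation). The acute-phase genes had a median of -0.38 there with 0 of 24 called (3 adjusted over the list alone, adjusted p = 1.6e-06, and adjusted p = 0.70 with an estimated correlation). In females the interferon response genes had a median of 0.20 with 0 of 22 called (2 higher adjusted over the list alone, adjusted p = 1.2e-07, and adjusted p = 0.73 with an estimated correlation). Of the 663 genes that differed in rsl null liver, 15 were called in the opposite direction with the Rsl1 transgene and 0 in the same (1.52 and 1.3 expected by chance), and 196 and 5 with the Rsl2 transgene (46.2 and 34.6). These counts too share the rsl null arrays, which by itself favours opposite changes. Across genes r was -0.462 for Rsl1 and -0.438 for Rsl2, against -0.502 and -0.501 in simulated unchanged groups that share these arrays. The simulated r does not depend on the size of the noise, so it cannot tell how much of the opposition comes from sharing. The covariances were -0.0173 and -0.0216, against -0.00558 and -0.0056 in the simulation. With those arrays split, r was -0.278 and -0.174 for Rsl1 and -0.322 and -0.192 for Rsl2. In these splits 0 and 0 were opposite for Rsl1 (0.105 and 0.0643 expected by chance). For Rsl2 8 and 14 were opposite (0.486 and 3.35 expected), with 0 and 3 in the same direction (0.432 and 2.79 expected).

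None of the preset targets tested here passed limma's test in a comparison of genotypes within 1 sex. Mup3, Mup5 and 1418021_at did not pass in the sex difference of wild type either (-0.21, -0.08 and -0.27). Mup3 (13.74 to 14.17) and 1418021_at (12.9 to 13.57) read close to the brightest probe set of an array (14.98 to 15.11). For these probe sets, not passing does not show that Rsl leaves them unchanged. Of the 10 genes on the preset list, 2 had a probe set with 1 symbol, so most Mup genes were not tested by name. In rsl null against wild type, Cyp2d9 was at 0.14 in males (adjusted p = 0.90) and 0.40 in females (adjusted p = 0.74), Mup10 at -0.17 and 0.19 (adjusted p = 0.71 and 0.74), Mup3 at -0.12 and -0.04 (0.53 and 0.89), Mup5 at -0.11 and -0.15 (0.59 and 0.52) and 1418021_at at 0.05 and 0.07 (0.87 and 0.89). With the Rsl1 transgene Cyp2d9 was at -0.12 in males (adjusted p = 0.97), Mup10 at 0.07 and 0.08 (0.96 and 0.89), Mup3 at 0.13 and 0.25 (0.81 and 0.26), Mup5 at -0.06 and 0.01 (0.91 and 0.97) and 1418021_at at -0.33 and -0.14 (0.58 and 0.65). With the Rsl2 transgene Cyp2d9 was at -0.15 and 0.60 (adjusted p = 0.87 and 0.46), Mup10 at 0.14 and 0.00 (0.76 and 0.99), Mup3 at 0.16 and 0.11 (0.39 and 0.55), Mup5 at 0.00 and 0.01 (0.99 and 0.97) and 1418021_at at -0.26 and -0.28 (0.28 and 0.24). Rsl1 was at 0.10 and -0.01 with the Rsl1 transgene (adjusted p = 0.94 and 0.98) and at -0.02 and 0.00 with the Rsl2 transgene (0.96 and 1). Zfp429 was at -0.93 in rsl null females (adjusted p = 0.58) and at 0.01 and 0.17 with the Rsl1 transgene (1 and 0.93). In the interactions of rsl null, Rsl1 and Rsl2 with sex, Cyp2d9 was at 0.25, 1.11 and 0.76 (adjusted p = 0.91, 0.90 and 0.98) and Mup10 at 0.36, 0.01 and -0.13 (0.69, 1 and 1). There Mup3 was at 0.08, 0.12 and -0.05, Mup5 at -0.05, 0.07 and 0.01, 1418021_at at 0.01, 0.20 and -0.02, Rsl1 at -0.13, -0.11 and 0.02 and Zfp429 at -0.56, 0.16 and -0.17, each with adjusted p of 0.85 or more. Between the transgenes Cyp2d9 was at 0.04 in males and 0.39 in females, Mup10 at -0.06 and 0.08, Mup3 at -0.03 and 0.14, Mup5 at -0.06 and 0.00, 1418021_at at -0.07 and 0.14 and Rsl1 at 0.13 and -0.01, each with adjusted p of 0.87 or more.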

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

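Of the tests in this part, the enrichment of called genes near Rsl1 and the counts over other splits of the arrays were fixed first, and the tests of a second block of genes, RNA quality, time of day, genotype, shared background and pancreas RNA were chosen only after the results were seen.

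The 3 averaged comparisons were fitted to their 8 arrays alone with sex as a covariate, for each of the 34 splits into 4 and 4 arrays. The real split called 129 genes for rsl null against wild type, 160 for the Rsl1 transgene and 2336 for the Rsl2 transgene, and the highest of the other splits called 1 in each, so that 1 of the 34 splits, the real one, gave as many genes. Of the 34 splits, 18 hold the sexes in balance as the real one does, and these 18 alone are too few for a share under 0.05.

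The genes that differed between rsl null and wild type were not spread evenly among all genes. Of the 100 tested genes nearest to Rsl1, 11 were called (11%), among them Zfp874a, Zfp729a, Prxl2c and Slc35d2, against 649 of 13501 elsewhere (4.81%, odds ratio 2.45, 95% confidence interval 1.17 to 4.62, Fisher's exact test p = 0.0091), which is consistent with alleles of the donor strain carried along with rsl. By sex, a count not fixed first, 12 of these 100 genes were called in males (odds ratio 3.63, Fisher's exact test p = 3e-04). In females 6 were called, against 24 of 13501 elsewhere (odds ratio 35.8, 95% confidence interval 11.7 to 92.6, Fisher's exact test p = 7e-08). Away from Rsl1, 4 overlapping runs of 50 genes, between Rhog and Adm, tied for the most called genes at 11 (permutation p = 0.034, median of the shuffles 9). These runs may mark another donor block or a gene family that changes or cross-hybridises together, and these possibilities were not separated. With the 3' to 5' actin difference as a covariate the differences of the called genes were 0.919 of their size at the median (quartiles 0.728 to 1.12). The standard error grew from 0.0908 to 0.143, and 24 genes passed in place of 663. What part of the loss each of these gave was not separated, so that RNA quality cannot be told apart from genotype in this comparison. Of the 11 called genes near Rsl1, 0 were called in the opposite direction with the Rsl1 transgene and 1 with the Rsl2 transgene. Hddc3 (8.07 to 8.44) and Tpmt (11.46 to 11.71) stayed at the rsl null level in the transgenic arrays. Tpmt and Cap2 lie on the chromosome of Rsl1, and Hddc3, Crym and Denn2b on that of Trim30d. Whether donor alleles reach these genes too was not tested. Of all 663 genes 15 and 196 were opposite with Rsl1 and Rsl2, but these counts share the rsl null arrays. An effect of the Rsl genes themselves on the genes outside these regions stays open.

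The clock genes differed between wild type and rsl null. Across the 17 clock genes, the difference of rsl null from wild type in males and the difference between the wild-type female arrays, replicate 2 minus replicate 1, had Pearson's r = 0.952 (Spearman's rho 0.944, permutation p = 1e-05, the smallest that these permutations can give; genes are not independent replicates), which is consistent with livers taken at other hours of the day. Wild-type female replicate 2 had a clock index of 2.93, near the rsl null arrays, while its Zfp874a (8.03) was at the wild-type level (7.73 to 8.01 in the 3 others, 4.34 to 4.57 in the 12 arrays of other genotypes), which argues against a mislabelled genotype, and its Gm7969 (7.36) and Hddc3 (5.80) lay outside the 3 other wild-type arrays (8.65 to 9.07 and 5.17 to 5.65) but nearer to them than to the other genotypes (3.37 to 3.91 and 8.01 to 8.47). An effect of genotype on the clock cannot be told apart from the hour of collection, which is not given in the sources used here: 3 of the 4 wild-type arrays lay below the 12 others, but the Rsl2 transgenic males (1.38 and 2.34) lay below wild-type female replicate 2 and the rsl null arrays (3.03 to 3.83). With the clock index as a covariate 20 genes passed in place of 663, 13 of them shared. The median size of the differences went from 0.435 to 0.305 and the standard error from 0.0908 to 0.161. For Rsl2 in males 45 passed in place of 286, while the differences kept 0.95 of their size at the median (quartiles 0.843 to 1.03). This loss by itself neither shows nor excludes an effect of the hour, as the index differs here too (3.17 and 3.24 in rsl null males).

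Of the 58 genes called with the Rsl1 transgene, 57 were called in the same direction with the Rsl2 transgene. With the actin covariate 0 of these 58 passed, at 0.924 of their size at the median (quartiles 0.866 to 0.963, standard error from 0.0901 to 0.112). The actin difference averaged 2.18 in rsl null females and 1.80 in females labelled Rsl1 transgene, so in females RNA quality cannot be told apart from the Rsl1 transgene. In males these means were closer, at 1.91 ± 0.10 in rsl null and 1.95 ± 0.08 with the label Rsl1 transgene. Retreg3 and Xrn1, called in those males, lost their calls with the covariate. For Rsl2 in females 5 of the 82 passed though they kept 0.978 of their size (quartiles 0.93 to 1.04). That loss by itself neither shows nor excludes RNA quality. The averaged Rsl2 differences kept 0.995 of their size at the median (quartiles 0.925 to 1.07). There 1075 genes passed, 937 shared with the 1661, which argues against RNA quality as the whole cause of that change. Without rsl null female replicate 2, the pool with pancreas RNA, 1110 genes passed and 963 of the 1661 were shared, which argues against that pool as the whole cause. A batch or background that the transgenic mice share cannot be told apart from the transgenes: across genes, Rsl2 transgene minus rsl null and Rsl1 transgene minus wild type, which share no array, had r = 0.261 (-0.0346 in males, 0.525 in females), and Rsl1 transgene minus rsl null and Rsl2 transgene minus wild type had r = 0.405 (0.266 and 0.409). An effect common to Rsl1 and Rsl2 stays open and untested. For some shared falls the transgenic arrays did not move toward wild type, which is Rsl/Rsl. Setd5 read 7.16 to 7.26 in wild type, 7.09 to 7.35 in rsl null and 6.21 to 6.54 in the transgenic arrays. Xrn1 read 7.05 to 7.21, 7.12 to 7.37 and 6.11 to 6.80. Of the 58 genes, 15 were called in the opposite direction in rsl null against wild type.

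A test of the difference between the sexes singled out 12 genes in rsl null against wild type, as the female minus the male effect: Ccdc25 at 2.17, Rdh11 at 1.78, Lgals1 at 1.73, Fmn1 at 1.5, Hmgcs1 at 1.32, Pltp at 1.31, Sqle at 1.21, Cyp51 at 1.07, Pmvk at 1.05, Idi1 at 1.04, Fdft1 at 1.01 and Mmab at 0.96. The same test singled out the cholesterol synthesis list there, with a median of 0.77 (adjusted p = 1.1e-18, and adjusted p = 0.087 with an estimated correlation). For the Rsl2 transgene it singled out Mt1 at -4.25 and the acute-phase list with a median of -0.65 (adjusted p = 1.9e-14, and adjusted p = 0.30 with an estimated correlation). Of 4756 probe sets above the filter with no gene symbol or more than 1, limma called 135 (2.84%) for rsl null against wild type, 41 (0.862%) for the Rsl1 transgene and 518 (10.9%) for the Rsl2 transgene, averaged over the sexes, against 3.81%, 0.462% and 10.5% of the probe sets with 1 symbol. The largest differences were 1.81 (1439200_x_at), -2.32 (1443353_at) and -2.41 (1449525_at).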

How the results depend on the processing

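Of the alternatives below, both doubted arrays left out, the clock index and the actin difference as covariates and eBayes with trend only were chosen after the data were seen. The 509 results for named genes had 7044 values under alternatives other than leaving out an array: 6065 kept direction and side of the threshold, 951 kept direction and lost the call, 10 gained it and 18 reversed. With each array left out, 1805 of 2880 kept both, 1067 lost the call, 8 gained it and 0 reversed. Neither scaling moved the median difference of all genes by over 0.1. Counts of called genes that moved by over 1.5 times follow by setting, and the cause was not tested except where fewer arrays or a stricter threshold give it by construction. Signal close to background limits dim genes such as Rsl1 and Zfp429.

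With each array left out in turn the counts ran from 245 to 957 for the sex difference, for rsl null from 81 to 458 in males, 11 to 438 in females and 203 to 1072 averaged, for Rsl1 from 0 to 2, 0 to 50 and 14 to 78, and for Rsl2 from 1 to 97, 2 to 93 and 277 to 1178. The interactions ran from 0 to 58 (rsl null), 0 to 38 (Rsl1) and 0 to 41 (Rsl2), and Rsl1 against Rsl2 from 0 to 4 in males and 0 to 0 in females.

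With adjusted p under 0.01 the counts were 239 for the sex difference, 135 (males) and 137 (averaged) for rsl null, 0, 0 and 15 for Rsl1 in males, females and averaged, 20, 4 and 267 for Rsl2, and 0 for the rsl null and the Rsl2 interaction. With at least 1.5-fold they were 398 for the sex difference, 315 (males) and 193 (averaged) for rsl null, 26 for Rsl1 averaged, and 170 (males) and 159 (averaged) for Rsl2. With arrays of the compared groups only they were 162 for the sex difference, 9 (females) and 235 (averaged) for rsl null, 6, 0 and 144 for Rsl1, 686, 0 and 2551 for Rsl2, 3 for the rsl null and 4 for the Rsl2 interaction. Array weights gave 190 for the sex difference, 31 (males) and 199 (averaged) for Rsl1, 1699, 349 and 3129 for Rsl2, 5 for the rsl null and 6 for the Rsl2 interaction. Trend and robust gave 5, 31 and 135 for Rsl1, 166 for Rsl2 in females, and 22, 4 and 6 for the rsl null, Rsl1 and Rsl2 interactions, and trend alone 7 (males) and 28 (females) for Rsl1 and 5 for the Rsl2 interaction.

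Centring on the medians gave 1, 32 and 91 for Rsl1, 518 (males) and 165 (females) for Rsl2 and 5 for the Rsl2 interaction, and quantile normalizing again 4 for Rsl1 in males, 147 for Rsl2 in males and 6 for the rsl null interaction. A filter at log2 of 7 gave 4 (males) and 97 (averaged) for Rsl1 and 178 for Rsl2 in females, and no filter 5 for the Rsl2 interaction. The mean of all probe sets gave 9 for Rsl1 in females, 7 for the rsl null and 0 for the Rsl2 interaction, and leaving out _x_at and _s_at probe sets 7 for Rsl1 in females and 0 for the Rsl2 interaction.

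With both doubted arrays left out the counts were 18 (females) and 314 (averaged) for rsl null, 5, 132 and 217 for Rsl1, 588 (males) and 255 (females) for Rsl2, and 59, 27 and 33 for the rsl null, Rsl1 and Rsl2 interactions. The clock index as a covariate gave 28, 11 and 20 for rsl null, 0 (males) and 25 (females) for Rsl1, 45 (males) and 267 (females) for Rsl2, and 33 and 0 for the rsl null and Rsl2 interactions. The actin difference gave 310, 11 and 24 for rsl null, 0, 0 and 0 for Rsl1, 154, 5 and 1075 for Rsl2, and 0 and 0 for the rsl null and Rsl2 interactions. In the 7 comparisons where this was measured, the called differences kept 0.919 to 0.995 of their size at the median with the actin difference and 0.727 to 1 with the clock index.

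Camera's 120 calls became 3 with an estimated correlation. Of the rsl null changes, the 15 opposite with Rsl1 became 55 with both doubted arrays left out, 0 in males only, 0 in females only, and 0 and 0 with the rsl null arrays split. The 196 opposite with Rsl2 became 60 in males only, 1 in females only, and 8 and 14 with the arrays split.

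Reversed with the clock index as a covariate were, in rsl null against wild type, Coq10b (0.00 in males, -0.24 averaged), Arntl (0.13 in males), Per1 (-0.09 in males, -0.05 averaged), Ciart (-0.12 in males, -0.17 averaged), and averaged Per2 (-0.48), Clock (0.02), Nfil3 (0.24), Nr1d2 (-0.05), Tef (-0.26) and Dnaja1 (-0.01). For the clock genes the covariate is built from these genes or their partners. With the mean of all probe sets Prxl2c (0.08, rsl null females) and Hadhb (0.21, Rsl2 averaged) reversed, and with _x_at and _s_at probe sets left out Erdr1 (-0.04, rsl null averaged), Ctse (-0.40, Rsl1 females) and Hamp2 (-0.06, sex difference). The cause was not tested.

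With a replicate block the counts were 776 for the sex difference, 470, 30 and 621 for rsl null in males, females and averaged, 0, 14 and 57 for Rsl1, 235, 72 and 1604 for Rsl2, 11, 0 and 0 for the interactions of rsl null, Rsl1 and Rsl2 with sex, and 0 and 0 for Rsl1 against Rsl2. Under the replicate block camera made 119 calls, and 13 and 187 rsl null changes were opposite with Rsl1 and Rsl2. Replicate numbers did not pair the arrays across groups: in 28 pairs of groups, the correlation of array deviations ran from -0.222 to 0.276 with a median of 0.00615.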

Other observations

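The transgenic arrays as a set, the set test over 100 random splits and the values per array below were chosen only after the results were seen. In all 8 transgenic arrays 73 genes read higher and 43 lower than in all 8 other arrays, 116 in all, against a median of 1 and a highest of 14 over 100 random splits into 8 and 8 (2.12 expected by chance). These random splits mix arrays of the same genotype, while the real split keeps each genotype whole. They treat the arrays as interchangeable, as does the 2.12, and other pairings of whole genotypes were not counted. Lonrf3, Ppp1r3b, Clec2d, Xrn1, Defa39 and Setd5 were among the lower ones, and Agfg2, Gsdme, Mpst, Foxp1, Chtf8 and Bbip1 among the higher ones. Sult2a2, a sulfotransferase of female liver, varied within the female groups. It read 12.01 and 11.98 in wild type, 13.00 and 9.57 in rsl null, 4.79 and 9.61 with the Rsl1 transgene and 4.46 and 8.66 with the Rsl2 transgene. Cyp2d9 read 10.97 to 12.98 in the 8 female arrays and 13.55 to 13.81 in the 8 male arrays.

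Other lists held called genes. In the sex difference of wild type, 2 of 22 interferon response genes rose (6 adjusted over the list alone, adjusted p = 4.6e-05, and adjusted p = 0.33 with an estimated correlation), and 2 of 15 stellate cell markers, Lum by 0.75 and Col1a2 by 0.43 (2 adjusted over the list alone, adjusted p = 0.00069, and adjusted p = 0.17 with an estimated correlation). Of 23 steroid and sulfate conjugation genes 6 rose and 6 fell (6 and 6 adjusted over the list alone, adjusted p = 0.73), and of 20 bile acid genes 1 rose and 4 fell (2 and 5 adjusted over the list alone, adjusted p = 0.11). Of 16 growth hormone and STAT5 genes 1 fell (3 rose and 1 fell adjusted over the list alone), and of 16 cell cycle genes 1 rose. In rsl null against wild type averaged over the sexes, 3 of 19 xenobiotic genes fell (1 rose and 4 fell adjusted over the list alone, adjusted p = 0.013, and adjusted p = 0.70 with an estimated correlation), the heme oxygenase Hmox1 at -0.47 and Gclc, an enzyme of glutathione synthesis, at -0.58. Of 13 heat shock genes 2 rose (2 adjusted over the list alone, adjusted p = 0.032, and adjusted p = 0.70 with an estimated correlation), Dnaja1 by 0.34 and Hspa1b by 0.98. Of 20 genes of the urea cycle and amino acid breakdown 4 fell (5 adjusted over the list alone, adjusted p = 0.13): Hal fell by 0.60, Cbs fell by 0.48, Nags fell by 0.34 and Cth fell by 0.26. Of the growth hormone and STAT5 genes 2 fell (3 adjusted over the list alone, adjusted p = 0.27), Stat5b at -0.56 and Cux2 at -0.49.

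With the Rsl2 transgene, averaged over the sexes, Trib3 rose by 0.90, 1 of 20 genes of endoplasmic reticulum stress called (1 adjusted over the list alone, adjusted p = 0.097), and 2 of 17 genes of gluconeogenesis and fasting rose (2 adjusted over the list alone, adjusted p = 0.97). Of 15 stellate cell markers Col3a1 and Pdgfrb rose by 0.51 and 0.72 (2 adjusted over the list alone, adjusted p = 0.24), of 15 endothelial markers Lyve1 by 0.54 (1 adjusted over the list alone, adjusted p = 0.14), and of 6 adipose markers Fabp4 and Lpl by 0.88 and 0.59 (2 adjusted over the list alone, adjusted p = 0.89). Of 12 lymphocyte markers 2 fell (4 adjusted over the list alone, adjusted p = 0.087), and of 13 hepatocyte markers 1 rose and 1 fell, Apob at -0.44 (1 and 1 adjusted over the list alone, adjusted p = 0.27). Of 9 neutrophil and erythroid markers 0 were called (2 rose adjusted over the list alone, adjusted p = 0.66), and of 8 bile duct markers 0 (0 adjusted over the list alone, adjusted p = 0.066). Across the 15 contrasts camera called none of the adipose, bile duct, cell cycle, hepatocyte, KRAB zinc finger, lymphocyte and neutrophil and erythroid lists. It called the Kupffer cell list in 13, the cholesterol list in 11, and the acute-phase and the interferon list in 10 each, and with an estimated correlation 0 of these 4 lists in any contrast.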
